A study of Mus musculus with 10 samples.

How the data were processed

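Messenger RNA from 2 mouse cell lines was measured on 10 Illumina mouse expression bead arrays, with biotin-labelled complementary RNA, per the labels. The values used were the deposited background-subtracted, normalized probe intensities, 1 linear value for each of 45281 probes on each array. The authors' background subtraction and normalization method was not given in the sources used here. GenomeStudio 2011.1 is named in the submitters' processing notes, with no role stated. The deposited intensities were checked and had nearly the same distribution on every array, with a median of 5.08 to 5.10 and an upper quartile of 83.9 to 84.2, and between 35.49% and 35.51% of values lay below 0. A further 20 value columns, which belonged to 2 slides holding 6 and 4 arrays, could not be tied to samples by their names and were not used, so neither their detection p-values nor the slide entered any test.

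Groups followed the labels: 3 adipocyte monolayer, 3 adipocyte bilayer, 2 macrophage monolayer and 2 macrophage bilayer samples. The design written before the data were examined assumed scanner signals with detection p-values and a normexp correction with quantile normalization. Because the values tied to samples were already background-subtracted and normalized, neither step was applied, and log2(intensity + 16) was tested with intensities below 0 set to 0. This departs from the written design. Fold changes are differences on that scale and understate the change of dim genes.

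Probe names came from the platform annotation, in which 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of these, 34807 were found by gene identifier in a RefSeq gene table, and 0 symbols needed updating. Probes with several symbols or none were left out. The array held 19057 genes. In each comparison a gene was represented by the probe with the highest mean among its probes that passed the noise filter described next. Among genes past the threshold, another probe of the same gene pointed the other way for 106 genes in adipocytes, 5 in macrophages, 28 in the difference of the responses and 662 in the comparison of the lines. That other probe itself passed the threshold in the opposite direction for 1, 0, 0 and 166 of them.

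A noise bound of 10.9 intensity units was set at the 99th percentile of the sizes of the values below 0. Genes were tested where the probe exceeded the bound on at least 2 arrays of the cell line compared, or of all 10 arrays for tests across lines. A gene not above the bound on any array of a group has only a bound there. Its change is given as at least N-fold, computed against the mean of the higher of the noise bound and its own value on each array of that group. Between 18977 and 18983 probes, or 41.9%, exceeded the bound on each array.

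Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 10 arrays and 4 groups, with eBayes and an intensity trend of the prior variance. The spread of each gene was thus pooled over the 4 groups, so a p-value in one line rests also on the scatter of the other line. All tests are two-sided, and adjusted p is limma's with Benjamini-Hochberg adjustment, called at 0.05. The comparisons were bilayer against monolayer in each line, the difference between those responses (adipocyte minus macrophage), and adipocytes against macrophages in monolayer. Standard errors (SE) are on the log2 scale. Values after ± are standard deviations (SD) of intensities.

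A total of 22 gene lists was fixed before the data were examined. They were adipocyte identity, macrophage identity, fibroblast and preadipocyte matrix, hypoxia response, glycolysis, oxidative phosphorylation, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, LXR targets and sterol efflux, lysosome, interferon response, inflammatory cytokines and NF-kB targets, acute phase, alternative macrophage activation, immediate early genes, proliferation, amino acid and integrated stress response, endoplasmic reticulum stress, heat shock, NRF2 targets and metallothioneins, and ribosomal proteins. On the array the lists held 506 genes, of which 1 was in more than 1 list. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance without setting them against other genes. Some lists had a larger camera p with the estimated correlation although the estimate lay below 0.01, such as heat shock in macrophages (-0.055). A call lost in that setting therefore need not mean that the genes were correlated. Calls within a list were also counted with p adjusted over the list alone.

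The genes named were set by a rule fixed before the data were examined. For each bilayer comparison it took the 6 largest rises and 6 largest falls past the threshold with replicates of the groups not overlapping, the 2 members with the smallest p of each shifted list, and the smallest-p member of every other list with a member past the threshold. For the difference it took the 6 largest, and for the cell lines the 6 largest in each direction plus 2 members of each identity list. Predicted genes and clone names were skipped among the largest changes. Other genes named are said to have been chosen after their values were seen.

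The procedure was tested on simulated arrays with 50 genes changed at each log2 difference of 0.5, 1, 2 and 4. In the simulated adipocyte comparison 48%, 70%, 98% and 100% of these were called, and 11 of 176 calls were false. In the macrophage comparison 32%, 88%, 96% and 100% were called, with 5 of 166 false. In the difference of the responses 20%, 54%, 80% and 100% were called, with 3 of 135 false. In the comparison of the lines 20%, 74%, 98% and 100% were called, with 8 of 161 false. A shifted simulated list was found in each of the 4 comparisons, and 0 of 20 unshifted lists was called by camera in any of them, in simulated genes that vary independently. Each simulated gene had the same spread in all 4 groups, with no floor at 0. The rates of calls and false calls thus do not cover real genes near noise or with a spread that differs between the lines.

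Alternatives covered the offset, the noise filter, the handling of several probes, the arrays in the fit, the variance model, array weights, cyclic loess, the replicate number as a block, a 2-fold threshold, the set test and leaving out each array in turn. The sharing of RNA between layers was estimated as the median over 110 probes bright in monolayer macrophages and not above noise in monolayer adipocytes, and over 166 probes with the opposite pattern. The number of arrays limits the precision of every comparison.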

Results

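The experiment measured messenger RNA in 2 mouse cell lines grown alone or together. 3T3-L1 cells are fibroblast-derived cells that can be turned into fat-storing adipocytes, and here they were at day 8 of differentiation. RAW 264.7 cells are a macrophage line. In the bilayer, macrophages on a polycarbonate membrane with 0.4 µm pores were placed above adipocytes for 24 h, so that secreted molecules but not cells could pass. In the monolayer each line was grown alone, but the labels do not say whether those dishes held a membrane insert or the same volume of medium. A difference between bilayer and monolayer therefore includes any effect of the membrane, medium or total cell number. The question was how the lines communicate, read here as the change in gene expression that each shows in the presence of the other.

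There were 3 monolayer and 3 bilayer arrays of adipocytes and 2 monolayer and 2 bilayer arrays of macrophages, and this number limits the precision. Samples were pools of 5 dishes. The series record calls them biological replicates, but the labels do not say that they came from independent cultures, so the p-values measure only the spread between these samples, which may be technical. On every array 41.9% of probes exceeded the noise bound. Arrays of 1 group correlated at r = 0.988 to 0.991 across probes, arrays of the same line in different conditions at 0.986 to 0.990, and arrays of different lines at 0.838 to 0.844.

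Monolayer adipocytes and macrophages expressed the genes that define each cell type at very different levels. Scd1, a fatty acid desaturase, had an intensity of 23674 ± 2038 (SD, n = 3) in adipocytes and was at least 879-fold higher than in macrophages. Cidec, a lipid droplet protein, reached 17262 ± 589 (SD, n = 3) and was at least 642-fold higher, and the caveolar protein gene Cav1 was at least 614-fold higher. Laptm5, a lysosomal membrane protein of blood cells, had an intensity of 18262 ± 618 (SD, n = 2) in macrophages and was at least 679-fold lower in adipocytes. The actin regulator Coro1a, at 18402 ± 165 (SD, n = 2) in macrophages, was at least 685-fold lower. Lysozyme, encoded by Lyz2, was at 12780 ± 122 (SD, n = 2) in macrophages and lower in adipocytes, where it was above noise on 1 of 3 arrays (adjusted p = 2.96e-14).

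Of the other largest differences, Igfbp7, Serpinh1 and Col6a1, genes of secreted or matrix proteins and their folding, were at least 712-fold, 609-fold and 585-fold higher in adipocytes, and the adipogenin gene Adig at least 373-fold. The chemokine genes Ccl4 and Pf4, the creatine kinase gene Ckb and the leukocyte antigen gene Cd52 were at least 479-fold, 401-fold, 579-fold and 369-fold lower in adipocytes than in macrophages. All 20 adipocyte identity genes and all 27 fibroblast and preadipocyte matrix genes were higher in adipocytes, and all 27 macrophage identity genes and all 26 proliferation genes were lower. The same numbers were reached when adjusted over the list alone, and camera gave adjusted p = 2.28e-12, 9.78e-15, 3.6e-15 and 2.28e-12.

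Among metabolic genes, 19 of 20 fatty acid and triglyceride synthesis genes, 18 of 19 fatty acid oxidation genes and 24 of 27 oxidative phosphorylation genes were higher in adipocytes, with the same numbers adjusted over the list alone. Of 30 interferon response genes 20 were lower in adipocytes and 4 higher, and of 26 inflammatory cytokines and NF-kB targets 18 were lower and 4 higher, in total 24 and 22 adjusted over the list alone. In all, 8091 of 12324 genes differed between the lines by limma, 4061 higher in adipocytes and 4030 lower, and 13 of 22 lists shifted, 9 of them also with an estimated correlation. The 4 lost were cholesterol synthesis (adjusted p = 0.222 with an estimated correlation), acute phase (adjusted p = 0.0951), hypoxia response (adjusted p = 0.375) and glycolysis (adjusted p = 0.375).

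Genes of the hypoxia response, glycolysis, inflammation and the interferon response were higher in bilayer than in monolayer adipocytes. The largest rise among annotated genes was in Ampd3, an AMP deaminase, from an intensity of 46.9 ± 9.52 in monolayer to 345 ± 24.8 in bilayer (SD, n = 3 each), a 5.78-fold change (SE 0.11 in log2, adjusted p = 1.15e-10). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose 2.63-fold from 658 ± 42.6 to 1755 ± 77.9 (SD, n = 3 each). Hp, which encodes the acute phase protein haptoglobin, rose 3.39-fold from 3017 ± 257 to 10291 ± 1380 (SD, n = 3 each). Hmox1, the haem oxygenase gene, rose 3.45-fold from 1950 ± 233 to 6735 ± 188 (SD, n = 3 each). Cell division genes fell, among them Birc5, a survivin needed for chromosome segregation, by 0.70 on the log2 scale.

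Of 18 hypoxia response genes tested in adipocytes, 15 rose, 0 fell and 3 did not pass, with 17 past the threshold when adjusted over the list alone. The median log2 difference was 1.08, and camera gave adjusted p = 1.9e-23. Pdk1 rose by 1.40 (SE 0.08, adjusted p = 1.91e-09) and P4ha2, a collagen prolyl hydroxylase, by 1.42 (SE 0.08, adjusted p = 2.02e-09). Of 15 glycolysis genes, 13 rose and 2 did not pass, 13 also when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 1.47e-22). The enolase gene Eno2 rose 4.18-fold (adjusted p = 2.5e-07), and the phosphofructokinase gene Pfkl rose 2.14-fold from 3579 ± 378 to 7681 ± 798 (SD, n = 3 each). The phosphoglycerate mutase gene Pgam1 rose 1.99-fold from 1335 ± 71.9 to 2669 ± 171 (SD, n = 3 each). Depp1, a FOXO-regulated gene, rose 3.95-fold (adjusted p = 3.11e-05).

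Of 23 interferon response genes, 14 rose in adipocytes and 9 did not pass, with 15 past the threshold when adjusted over the list alone (median 0.55, camera adjusted p = 9.75e-15). Oasl2, an oligoadenylate synthetase-like gene, rose 4.85-fold from 37.5 ± 7.78 to 243 ± 34.6 (SD, n = 3 each), and the ubiquitin-like modifier gene Isg15 rose 2.25-fold (adjusted p = 4.49e-06). Of 18 inflammatory cytokines and NF-kB targets, 8 rose and 10 did not pass, with 10 past the threshold when adjusted over the list alone (median 0.51, camera adjusted p = 1.76e-10). Ccl2, a chemokine that attracts monocytes, rose 2.79-fold from 212 ± 37.6 to 614 ± 53.4 (SD, n = 3 each), and Nfkbie, an inhibitor of NF-kB, rose 2.89-fold. Of 16 acute phase genes, 7 rose and 1 fell, with 7 higher and 1 lower when adjusted over the list alone (median 0.50, camera adjusted p = 4.08e-07). Besides Hp, the oncostatin M receptor gene Osmr rose 3.64-fold from 336 ± 9.5 to 1268 ± 119 (SD, n = 3 each). These 5 lists kept their shift with an estimated correlation, at adjusted p = 0.00936 for hypoxia response, 0.00593 for glycolysis, 0.00256 for interferon response, 0.00593 for inflammatory cytokines and NF-kB targets and 0.015 for acute phase.

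Of 24 amino acid and integrated stress response genes, 9 rose and 1 fell, with 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.94e-07, adjusted p = 0.0832 with an estimated correlation). The pseudokinase gene Trib3 rose 2.22-fold and Ppp1r15a, a phosphatase subunit that restores translation, 2.62-fold. Of 18 immediate early genes, 8 rose and 10 did not pass, with 10 past the threshold when adjusted over the list alone (camera adjusted p = 8.43e-06, adjusted p = 0.152 with an estimated correlation). Among them Ier3 rose 2.53-fold and the transcription factor gene Egr3 2.33-fold. Of 22 NRF2 targets and metallothioneins, 5 rose and 2 fell, in total 7 also when adjusted over the list alone, and the list did not shift by camera (adjusted p = 0.398), though by fry its genes moved up on balance (adjusted p = 0.0133). Its median was -0.04 while its mean was 0.16. Of 18 endoplasmic reticulum stress genes, 2 rose and 5 fell, with 2 higher and 7 lower when adjusted over the list alone and no shift by camera (adjusted p = 0.151), though by fry they moved down on balance (adjusted p = 0.0015). The rise was led by Ddit3, a transcription factor of the integrated stress response, at 2.05-fold (adjusted p = 1.64e-06). The falls, named after their values were seen, were in the chaperone and folding genes Sdf2l1, Pdia3, Calr, Creld2 and Dnajc3.

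Of 25 proliferation genes in adipocytes, 14 fell, 0 rose and 11 did not pass, with 18 past the threshold when adjusted over the list alone (median -0.36, camera adjusted p = 1.82e-12, adjusted p = 0.0145 with an estimated correlation). Birc5 went from 603 ± 23.2 to 367 ± 32.2 (SD, n = 3 each), and Cdc20, an activator of the anaphase-promoting complex, fell by 0.70 (SE 0.09, adjusted p = 5e-05). Large falls were in the smooth muscle actin gene Actg2 (-1.21, SE 0.22, adjusted p = 0.00161) and the myosin light chain gene Myl9 (-1.08, adjusted p = 0.00111). The inositol transporter gene Slc5a3 (adjusted p = 0.0135), the transcription factor gene Irf5 (adjusted p = 6.23e-06) and L1td1 (adjusted p = 0.0165) also fell, and in bilayer they were above noise on 2, 2 and 1 of 3 arrays. Mdh1b was at least 1.55-fold lower in bilayer, where it was not above noise. The remaining large rises were in the nucleotide receptor gene P2ry6, at least 2.72-fold from below noise, and the semaphorin gene Sema3g, 3.65-fold (adjusted p = 2.61e-06).

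Genes of the fat cell programme passed the test about as often as all genes tested in adipocytes, of which 10.9% passed. Of 20 adipocyte identity genes, 2 fell and 18 did not pass, with 3 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0211, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.0517). By limma 9 of them had an unadjusted p under 0.05, against 2711 of all 11037 genes. Carbonic anhydrase 3, encoded by Car3, went from 2726 ± 219 to 1976 ± 206 (SD, n = 3 each, adjusted p = 0.00562), and the glycerol-3-phosphate dehydrogenase gene Gpd1 fell by 0.62 (adjusted p = 0.0196). Of 27 oxidative phosphorylation genes, 3 fell, with 5 past the threshold when adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.152 with an estimated correlation), including Ndufa4 (-0.24, adjusted p = 0.0148) and Sdhd (-0.38, adjusted p = 0.0149). Of 26 lysosome genes, 4 rose and 1 fell, in total 5 also when adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.071 with an estimated correlation). The cholesterol exporter gene Npc1 rose 1.37-fold and the cathepsin A gene Ctsa 1.34-fold. The adipocyte identity call was lost without monolayer replicate 3, bilayer replicate 1 or bilayer replicate 3 (adjusted p = 0.0729 to 0.0944), and the oxidative phosphorylation call without monolayer replicate 1 (adjusted p = 0.0564).

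Other lists did not shift in adipocytes by camera. Of 20 fatty acid and triglyceride synthesis genes (adjusted p = 0.801) 1 rose and 1, the lipogenesis regulator Thrsp, fell by 0.70 (adjusted p = 8.69e-05). Of 18 cholesterol synthesis genes (adjusted p = 0.306) 2 rose, led by the squalene epoxidase gene Sqle at 1.77-fold (adjusted p = 1.78e-06). Of 9 LXR targets and sterol efflux genes (adjusted p = 0.994) the lipid droplet gene Plin2 rose 1.51-fold. Of 13 alternative macrophage activation genes (adjusted p = 0.816) Tgm2, a transglutaminase gene, rose 1.42-fold, 1 other rose and 1 fell. Of 14 heat shock genes (adjusted p = 0.126) 2 fell, among them Hsph1 (-0.31, adjusted p = 0.0319), and by fry this list moved down on balance (adjusted p = 0.0111). Of 19 ribosomal protein genes (adjusted p = 0.816) Rpl22 rose 1.21-fold. Of 19 fatty acid oxidation genes (adjusted p = 0.801) 0 passed by limma, and 6 had an unadjusted p under 0.05. In these lists, in the order given, 2, 2, 1, 3, 2, 1 and 0 genes passed when adjusted over the list alone.

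Markers of other cell types were measured in the same arrays. Of 8 macrophage identity genes tested in adipocytes, Cd14, a lipopolysaccharide co-receptor that adipocytes also expressed in monolayer, rose from 260 ± 19.3 to 315 ± 20.5 (SD, n = 3 each, adjusted p = 0.0448), against 7287 in monolayer macrophages, and the list did not shift (adjusted p = 0.801) and had 1 gene higher and 1 lower when adjusted over the list alone. The Cd14 call was lost without monolayer replicate 1 or 3 or bilayer replicate 2 or 3 (adjusted p = 0.116 to 0.156). Over 110 probes bright in macrophages and not above noise in monolayer adipocytes, the bilayer adipocyte arrays held a median 0.0151% to 0.0501% of the macrophage level. The monolayer adipocyte arrays gave -0.00784% to 0.00514%, near 0 by construction, since the shares are set against their mean. Of these probes 7 to 14 were above noise on a bilayer array, which the median does not show. On monolayer arrays none was, by the choice of the probes. Their median intensity was -0.95 to -0.64 on bilayer and -0.54 to -0.37 on monolayer arrays, so these values do not show an excess of macrophage RNA. Of 27 fibroblast and preadipocyte matrix genes, Acta2, a contractile actin gene, fell by 0.61 (adjusted p = 0.000278), with 3 higher and 2 lower when adjusted over the list alone and no shift (adjusted p = 0.801).

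In all, 1206 of 11037 genes differed between bilayer and monolayer adipocytes by limma, 626 higher and 580 lower, of which 91 and 12 changed at least 2-fold. The count was 687 without monolayer replicate 1, 779 without monolayer replicate 2 and 796 without bilayer replicate 2, and 609 with no filter on dim probes or 598 with no variance trend. Among the genes named, Gpd1, Hsph1, L1td1, Rpl22, Sdhd, Slc5a3, Ndufa4 and Cd14 lost their call without monolayer replicate 1, and all but Ndufa4 also without other arrays, at adjusted p = 0.0506 to 0.168. Of the 22 lists 11 shifted, 8 up and 3 down, and 6 did so with an estimated correlation. Other splits of the 6 arrays shifted up to 8 lists with the preset correlation and 0 with the estimated one. Each of those splits mixes the conditions unevenly, so part of the bilayer difference stays in it and the rest adds to the spread. These counts are thus not a rate of false calls.

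**Figure D1:**
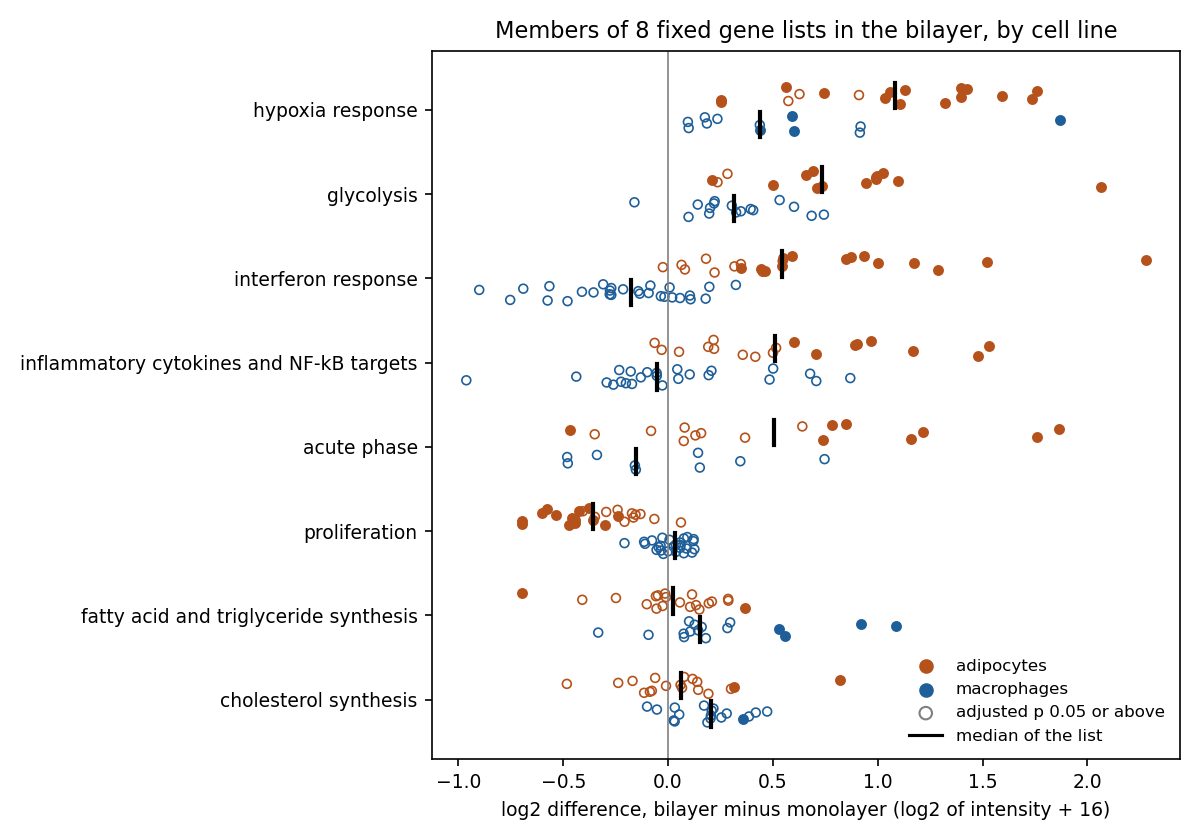
Log2 difference of bilayer minus monolayer (x axis) for each tested member of 8 fixed gene lists, adipocytes in orange and macrophages in blue, filled where adjusted p was under 0.05, with a black tick at each list's median. The hypoxia response median was 1.08 in adipocytes and 0.44 in macrophages, while the interferon response median was 0.55 in adipocytes and -0.18 in macrophages.

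A small set of genes was several-fold higher in bilayer than in monolayer macrophages. Arg1, the arginase that marks alternative activation, was not above noise in monolayer (0.592 ± 4.01) and reached 110 ± 3.58 in bilayer (SD, n = 2 each), at least 4.69-fold higher (adjusted p = 0.000248). Il1r2, the decoy receptor for interleukin-1, rose 5.86-fold from 26.7 ± 5.86 to 234 ± 39.3 (SD, n = 2 each, adjusted p = 0.000295). Tnfrsf9, a co-stimulatory receptor, rose 5.14-fold from 86.4 ± 6.44 to 510 ± 31.4 (SD, n = 2 each, adjusted p = 0.0328). The spread behind that p-value is pooled with the adipocyte arrays, where Tnfrsf9 was above noise on only some. The same pooling may make the SE of Arg1 and of Il1r2 too small, since adipocyte arrays, none above noise for either gene, add little scatter. Ndrg1, a hypoxia-induced gene, rose 3.66-fold from 310 ± 4.69 to 1180 ± 99.4 (SD, n = 2 each, adjusted p = 0.00156). Slc40a1, the iron exporter ferroportin, went from 2971 ± 32.3 to 1775 ± 234 (SD, n = 2 each, adjusted p = 0.0172).

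Rgcc, a cell cycle regulator, was at least 4.14-fold higher in bilayer macrophages from below noise, and the coagulation factor gene F13a1, above noise on 1 of 2 monolayer arrays, rose to 72.7 ± 19.5 (SD, n = 2, adjusted p = 0.014). Chd1, a chromatin remodeller, fell by 1.19 on the log2 scale (SE 0.21, adjusted p = 0.0162) and Sbsn fell by 0.78 (adjusted p = 0.0282). Sybu, the actin bundling gene Fscn1 and Epb41l1 were low in monolayer and not above noise in bilayer, at least 1.39-fold, 1.23-fold and 1.17-fold lower. The adipocyte hormone gene Adipoq behaved likewise, with an intensity of 15.5 in monolayer and 3.01 in bilayer macrophages against 22041 in monolayer adipocytes (adjusted p = 0.0156). It was the 1 of 7 adipocyte identity genes past the threshold, 2 when adjusted over the list alone, and the list did not shift (adjusted p = 0.713). Over 166 probes bright in adipocytes and not above noise in monolayer macrophages, bilayer macrophage arrays held a median 0.00126% to 0.00687% of the adipocyte level. That is within the -0.0118% to 0.0118% of the monolayer arrays, which centre on 0 by construction, so no share was measurable. Of these probes 9 to 10 were above noise on a bilayer array, which the median does not show, and by the choice of the probes none was on a monolayer array.

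Of 12 hypoxia response genes tested in macrophages, 4 rose and 8 did not pass, with 6 past the threshold when adjusted over the list alone (median 0.44, camera adjusted p = 1.07e-10, adjusted p = 0.0481 with an estimated correlation). Besides Ndrg1 they included Anxa2, a membrane-binding protein gene, which rose 1.51-fold from 8275 ± 521 to 12532 ± 181 (SD, n = 2 each). The 16 glycolysis genes shifted upward as a list, with a median of 0.31, or 0.26 with the 1 member not above noise in monolayer held at its bound (camera adjusted p = 1.72e-09, adjusted p = 0.0579 with an estimated correlation). By limma 0 of them passed over all genes, 10 had an unadjusted p under 0.05 and 10 passed when adjusted over the list alone. Tpi1 had a log2 difference of 0.53 (adjusted p = 0.108) and Pfkl of 0.39 (adjusted p = 0.129).

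Lipid synthesis lists shifted upward in macrophages. Of 16 fatty acid and triglyceride synthesis genes, 4 rose, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.09e-05, adjusted p = 0.0451 with an estimated correlation). The desaturase gene Scd2 rose 1.89-fold from 565 ± 71.8 to 1081 ± 22.6 (SD, n = 2 each, adjusted p = 0.000482) and the acetyl-CoA synthetase gene Acss2 1.47-fold (adjusted p = 0.0282). Of 18 cholesterol synthesis genes, 1 rose, the farnesyl diphosphate synthase gene Fdps at 1.28-fold (adjusted p = 0.0484), with 4 past the threshold when adjusted over the list alone (camera adjusted p = 1.09e-05, adjusted p = 0.117 with an estimated correlation). Insig1 had a log2 difference of 0.39 (adjusted p = 0.11).

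The 28 interferon response genes shifted downward in macrophages as a list (median -0.18, camera adjusted p = 0.00146, adjusted p = 0.0481 with an estimated correlation). By limma 0 passed over all genes, 7 had an unadjusted p under 0.05 and 3 passed when adjusted over the list alone. Oasl2 was at 212 ± 19.6 in monolayer and 125 ± 15.6 in bilayer (SD, n = 2 each, adjusted p = 0.135), and Oas2 had a log2 difference of -0.90 (adjusted p = 0.167). Of 20 NRF2 targets and metallothioneins, 1 fell, the glutathione synthesis gene Gclm, by 0.50 on the log2 scale (adjusted p = 0.0162), with 3 past the threshold when adjusted over the list alone (camera adjusted p = 0.00264, adjusted p = 0.0762 with an estimated correlation). Taldo1 had a log2 difference of -0.25 (adjusted p = 0.197), or -0.16 without monolayer replicate 2.

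Further lists shifted less firmly in macrophages. Of 27 lysosome genes, Lipa, the lysosomal acid lipase gene, fell by 0.67 (adjusted p = 0.0343), with 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.117 with an estimated correlation). Gpnmb had a log2 difference of -0.77 (adjusted p = 0.0623). Of 13 alternative macrophage activation genes, Arg1 and the cytokine signalling suppressor gene Socs2 (1.94-fold, adjusted p = 0.014) rose, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0485, adjusted p = 0.117 with an estimated correlation). Arg1, not above noise in monolayer, had by far the largest fitted log2 difference, 2.84, against a list mean of 0.32 and median of 0.16. The list was not tested on all arrays without Arg1. The 12 heat shock genes shifted downward (camera adjusted p = 0.0458, adjusted p = 0.117 with an estimated correlation), with 0 passing by limma, 3 at an unadjusted p under 0.05 and 1 when adjusted over the list alone. In that list Hspb8, not above noise in bilayer, had adjusted p = 0.161, and Hsph1 had a log2 difference of -0.28 (adjusted p = 0.38). The lysosome call was lost without monolayer replicate 2 or bilayer replicate 1 or 2 (adjusted p = 0.0656 to 0.385), the alternative activation call without monolayer replicate 1 or bilayer replicate 1 or 2 (0.0609 to 0.713), and the heat shock call without any 1 of the 4 arrays (0.0754 to 0.427).

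The 27 macrophage identity genes held 0 that passed by limma and 2 with an unadjusted p under 0.05, and that list did not shift (adjusted p = 0.745). Inflammatory cytokines and NF-kB targets, acute phase, proliferation, endoplasmic reticulum stress, fatty acid oxidation, LXR targets and immediate early genes all had adjusted p = 0.799, against 0.187 for the amino acid and integrated stress response, 0.428 for ribosomal proteins and 0.889 for oxidative phosphorylation. No member of these lists passed by limma over all genes, while 4 LXR targets, 2 higher and 2 lower, and 1 acute phase gene passed when adjusted over the list alone, and the unadjusted counts ranged from 0 for proliferation to 6 for NF-kB targets. Of the 4 fibroblast and preadipocyte matrix genes tested, too few for a list test, Timp1, an inhibitor of metalloproteases, was at least 1.13-fold higher in bilayer (adjusted p = 0.0397).

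In all, 70 of 10326 genes differed between bilayer and monolayer macrophages by limma, 52 higher and 18 lower. The count was 36 without monolayer replicate 1, 25 without monolayer replicate 2, 17 without bilayer replicate 1 and 11 without bilayer replicate 2, and 168 when only the macrophage arrays were fitted. The calls of Acss2, Chd1, Fdps, Gclm, Lipa, Sbsn, Slc40a1 and Tnfrsf9 were lost without any 1 of the 4 arrays (adjusted p = 0.0527 to 0.349), and those of Ndrg1, Fscn1 and Sybu without bilayer replicate 1 or 2 (0.0533 to 0.0751 for Ndrg1 and Fscn1, 0.174 to 0.182 for Sybu). Without a monolayer array Fscn1 and Sybu could not be tested. Calls were also lost for F13a1 without monolayer replicate 1 or either bilayer array (0.0533 to 0.164), Socs2 without monolayer replicate 2 or either bilayer array (0.073 to 0.212) and Epb41l1 without either monolayer array or bilayer replicate 1 (0.169 to 0.649). The Anxa2 call was lost without bilayer replicate 2 (0.0533). The Adipoq call was lost without bilayer replicate 1 (0.229) and that of Timp1 without monolayer replicate 2 (0.263), and for both of these genes only 2 of the 4 fits could be run. Those of Il1r2 and Scd2 held without each array in turn, and those of Arg1 and Rgcc without either monolayer array, while without a bilayer array these genes were above noise on too few arrays to be tested. Of 21 lists 9 shifted, 5 up and 4 down, and 3 did so with an estimated correlation.

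**Figure D2:**
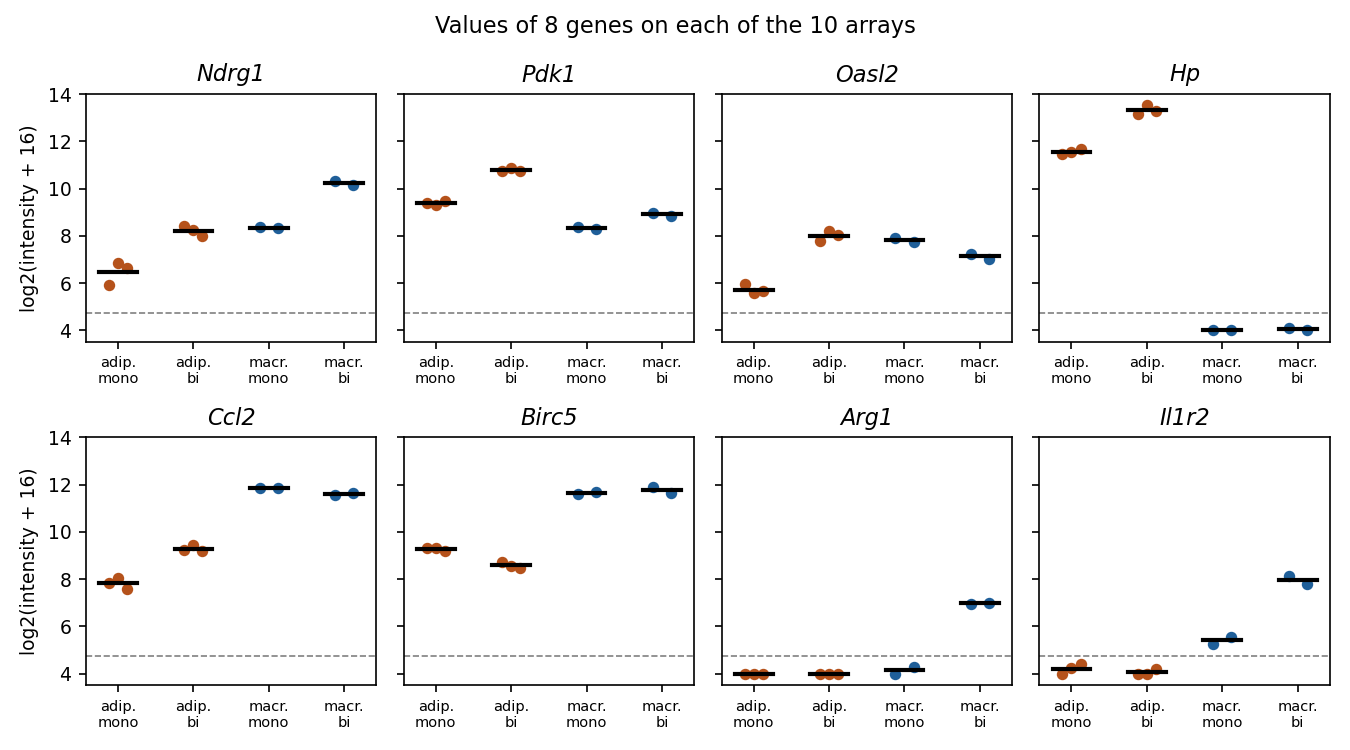
Log2(intensity + 16) (y axis) of Ndrg1, Pdk1, Oasl2, Hp, Ccl2, Birc5, Arg1 and Il1r2 on each of the 10 arrays by cell line and condition, with points for arrays, black lines for group means and a dashed line at the noise bound. Ndrg1 rose in both lines (1.76 in adipocytes and 1.87 in macrophages), whereas Arg1 rose in macrophages by at least 4.69-fold.

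Some genes rose in both lines. Of 9363 genes tested in both, 18 rose in both, against 2.86 for independent lists of these sizes. The log2 differences share no arrays, but the spread of each gene was estimated from all 10 arrays for both comparisons. A gene with a small spread thus passes more easily in both, so the lists are not independent and 2.86 is only a reference. In log2, and named after their values were seen, the genes that rose in both included Ndrg1 (1.76 in adipocytes and 1.87 in macrophages), Depp1 (1.98 and 1.63), Plod2, a collagen lysyl hydroxylase gene (1.09 and 1.16), Pdk1 (1.40 and 0.59), and Fam162a (0.97 and 0.45). A further 2 fell in both, Id1 and Tfrc, against 1.05 for independent lists. Opposite changes were found for 5 genes, named after their values were seen. Lipa and Col18a1 rose in adipocytes and fell in macrophages, against 1.07 genes for independent lists, and Gpat3, Gper1 and Mid1ip1 fell in adipocytes and rose in macrophages, against 2.79. Across all 9363 genes, which are not independent replicates, the log2 differences correlated at Pearson r = 0.044 and Spearman rho = 0.018. Depp1 was uneven in macrophages, and without bilayer replicate 2 its log2 difference there was 0.92 (adjusted p = 0.267). Of the macrophage calls named here, only that of Plod2 held without each array in turn, and the others were lost without at least 1 array. For Gper1 and Col18a1 only 2 of these fits could be run. Without a bilayer array another probe represented Gpat3, and its log2 differences were 0.27 and 0.64, against 1.56 in the main fit. The rise of Gpat3 thus rests on 1 probe. In adipocytes the calls of Gpat3, Gper1, Mid1ip1 and Col18a1 were lost without 3 to 5 of the 6 arrays (adjusted p = 0.0518 to 0.175). The count of 18 was 10 without adipocyte monolayer replicate 1, 6 without macrophage monolayer replicate 2, 4 without macrophage bilayer replicate 1 and 2 without macrophage bilayer replicate 2, and it was 8 with no filter on dim probes, 5 with no variance trend and 32 with each line fitted alone.

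Some single genes responded differently in the lines. Oasl2 rose in adipocytes and had a log2 difference of -0.69 (adjusted p = 0.135) in macrophages, a difference between the responses of 2.97 (SE 0.23, adjusted p = 1.22e-05). Ampd3 differed by 2.52 (SE 0.18, adjusted p = 5.96e-06). The responses of Arg1 and Il1r2, which were above noise on no adipocyte array, were lower in adipocytes (adjusted p = 0.00069 for each). That of Tnfrsf9, above noise on 1 of 3 adipocyte arrays in each condition, was also lower (adjusted p = 0.0472). That of the mitochondrial carrier gene Slc25a34 was higher in adipocytes (adjusted p = 0.00202), going from 95.3 to 320 there and from 19.8 to 7.93 in macrophages, where 1 of 2 bilayer arrays was above noise.

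Of 30 interferon response genes, 8 had a response that was higher in adipocytes, 14 when adjusted over the list alone (camera adjusted p = 1.34e-13). Of 26 proliferation genes, 4 had a lower response in adipocytes, 11 when adjusted over the list alone (adjusted p = 1.59e-08). Higher responses in adipocytes were found for 6 of 26 inflammatory cytokines and NF-kB targets (9 higher and 1 lower adjusted over the list alone), 5 of 16 acute phase genes with 1 lower (8 higher and 1 lower adjusted over the list alone) and 2 of 28 lysosome genes with 1 lower (4 higher and 2 lower adjusted over the list alone), and these 5 lists kept their shift with an estimated correlation. Higher responses were also found for 8 of 16 glycolysis genes (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.057 with an estimated correlation), 5 of 18 hypoxia response genes (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.0571 with an estimated correlation), 5 of 26 integrated stress response genes (7 higher adjusted over the list alone, adjusted p = 0.057 with an estimated correlation) and 4 of 22 NRF2 targets (4 higher adjusted over the list alone, adjusted p = 0.0823 with an estimated correlation). Of 20 fatty acid and triglyceride synthesis genes, 2 had a lower response in adipocytes (2 lower and 1 higher adjusted over the list alone, adjusted p = 0.057 with an estimated correlation). The 19 immediate early genes shifted as a list (adjusted p = 0.000269, adjusted p = 0.186 with an estimated correlation), with 0 passing by limma and 7 at an unadjusted p under 0.05, and fry gave adjusted p = 0.111. By fry alone, 3 further lists had lower responses in adipocytes on balance, alternative macrophage activation (adjusted p = 0.00115), endoplasmic reticulum stress (adjusted p = 0.0277) and fibroblast and preadipocyte matrix (adjusted p = 0.0432).

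In all, 315 of 12324 genes had a response that differed between the lines by limma, 185 higher and 130 lower in adipocytes, and 11 of 22 lists shifted, 5 of them with an estimated correlation. The gene count was 181, 183 and 203 without adipocyte monolayer replicate 1, adipocyte monolayer replicate 2 and adipocyte bilayer replicate 2. It was 142, 139, 98 and 127 without macrophage monolayer replicates 1 and 2 and bilayer replicates 1 and 2, and it was 104 with no filter on dim probes and 81 with no variance trend. The Tnfrsf9 call was lost without adipocyte monolayer replicate 1 or 3, adipocyte bilayer replicate 2 or 3, or any 1 of the macrophage arrays (adjusted p = 0.0769 to 0.185).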

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

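The tests of slides and runs, of adipocyte RNA in the macrophage layer and of fewer fibroblast-like cells were chosen only after the result was seen. The results here stand out because a test of the difference between the cell lines found the bilayer response, adipocyte minus macrophage, to differ. That test gave 315 genes by limma. Fitted differences on the scale of log2(intensity + 16) were 2.97 for Oasl2, -2.84 for Arg1, -2.71 for Il1r2, 2.52 for Ampd3, -2.40 for Tnfrsf9 and 2.22 for Slc25a34. The sizes for Arg1 and Il1r2, above noise on no adipocyte array, and for Tnfrsf9 and Slc25a34, above noise on only some arrays, cannot be ranked. The same test shifted 11 lists, with median log2 differences of 0.65 for interferon response, -0.41 for proliferation, 0.49 for glycolysis, 0.85 for hypoxia response, 0.27 for the amino acid and integrated stress response and 0.34 for inflammatory cytokines and NF-kB targets. The others were 0.61 for acute phase, 0.53 for immediate early genes (0.28 without adipocyte bilayer replicate 1), 0.19 for lysosome, -0.12 for fatty acid and triglyceride synthesis (-0.19 without adipocyte bilayer replicate 3) and 0.12 for NRF2 targets and metallothioneins. With an estimated correlation 5 of them shifted, and 6 did not: glycolysis (adjusted p = 0.057), hypoxia response (adjusted p = 0.0571), the amino acid and integrated stress response (adjusted p = 0.057), immediate early genes (adjusted p = 0.186), fatty acid and triglyceride synthesis (adjusted p = 0.057) and NRF2 targets and metallothioneins (adjusted p = 0.0823).

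The 6 adipocyte arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1206 genes by limma and the highest other split 0, with 2711 against at most 616 at an unadjusted p under 0.05. For lists, the real split shifted 11 and the highest other split 8. In each case 1 split, the real one, gave a result as large. The other splits mix the conditions unevenly, so they keep part of the bilayer difference and add the rest to the spread. Their counts are not what arrays without any difference would give.

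Hypoxia response and glycolysis lists shifted upward in both lines, though for glycolysis in macrophages with adjusted p = 0.0579 with an estimated correlation and 0 of 16 genes passing by limma, 10 at an unadjusted p under 0.05. RNA from the other cell layer would need a median share of 100% macrophage RNA for the rises in adipocytes, the value given to a gene that is no higher in macrophages or rose by more than the whole difference, and 62.0% adipocyte RNA for the rises in macrophages. The measured shares were at most 0.0501% and 0.00687%, which argues against both, in macrophages for hypoxia response genes only. The 62.0% is the median over the 4 hypoxia response genes called there, which needed 13.0% to 100%. No glycolysis gene was called in macrophages, so that list was not covered. Lower glucose in the shared medium could act on glycolysis genes and would lower the glucose-responsive genes Txnip and Arrdc4. Only 1 of 4 pairs of gene and line, Arrdc4 in adipocytes, fell at an unadjusted p under 0.05 by limma (-0.24, SE 0.09). Txnip in adipocytes and macrophages (0.27 and 0.35, unadjusted p = 0.0022 and 0.00267) and Arrdc4 in macrophages (0.25, SE 0.11, unadjusted p = 0.0448) rose. In macrophages both genes thus went against lower glucose. In adipocytes the 2 genes disagreed, so for both lines together the test decides neither way. A difference between slides or runs cannot be told apart from the conditions, because 0 value columns with slide positions could be tied to a sample, and the membrane, medium volume, total cell number and a response to co-culture stay open as untested.

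Interferon response genes rose in adipocytes and shifted downward as a list in macrophages. RNA from the other layer would need a median share of 100% macrophage RNA for the rises in adipocytes, against at most 0.0501% measured. Dilution of macrophage RNA by adipocyte RNA would need 11.6% for the median fall in macrophages, against at most 0.00687%. Both values argue against an exchange of RNA as the cause. Slides or runs and signals passing between the layers stay open, as untested.

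Proliferation genes fell in adipocytes. RNA from the other layer would raise them, because their median was -2.36 in log2 for adipocytes minus macrophages in monolayer. That argues against it. Fewer undifferentiated fibroblast-like cells could lower the fibroblast and preadipocyte matrix list as well, but its median of 0.0566 in bilayer minus monolayer adipocytes came from members that went both ways, and the contractile gene Acta2 in it fell by 0.61, so this explanation stays open. Slides or runs and a response to co-culture stay open too, as untested.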

How the results depend on the processing

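Cyclic loess, log2 at the noise bound with no offset, the stricter noise filter and the filter at an intensity of 50 were chosen after seeing the data. No shifted list or named gene among those refitted changed direction under any alternative run. Among unshifted lists, inflammatory cytokines and NF-kB targets, LXR targets and oxidative phosphorylation in macrophages pointed down by camera and up by fry. Heat shock between the lines did too. The balance of calls also turned, to 533 higher and 549 lower in adipocytes with the mean of all probes. Between the lines it was 4053 and 4082 with an offset of 50. The 2-fold threshold left 103 genes in adipocytes, 21 in macrophages, 94 in the difference of the responses and 4653 between the lines, fewer by construction. Testing every probe gave 12587 probes between the lines, more by construction. With no filter on dim probes the counts were 609 in adipocytes, 104 in the difference and 8 higher in both lines. With no variance trend they were 598, 81 and 5. Of the named macrophage genes, 13 lost their call and 17 kept their side of the threshold with no filter. With no variance trend 11 lost it, 2 gained it and 17 kept their side. Fitting each line's arrays alone gave 168 in macrophages, 50 of them among the 70, and 32 higher in both, for which no count for independent lists was computed. For these last 3 settings the cause was not tested. With an estimated correlation between genes 6 lists shifted in adipocytes, 3 in macrophages and 5 in the difference. Leaving out each array in turn gave 687 to 1056 genes in adipocytes, 11 to 36 in macrophages, 98 to 314 in the difference, 7373 to 7825 between the lines and 2 to 16 higher in both, and 10 to 11, 6 to 7 and 11 to 13 lists. Where 1 macrophage array was left in a group, it was assumed to vary like the other groups. Of the named genes' results under alternatives other than leaving out arrays, 490 kept their side of the threshold and 22 lost it in adipocytes, 282 kept, 58 lost and 12 gained it in macrophages, and 59 kept and 7 lost it in the difference. All 140 between the lines kept it. On leaving out arrays 233 kept and 25 lost it in adipocytes, 56 and 50 in macrophages and 50 and 8 in the difference, and 70 of 70 kept it between the lines. Whether the replicate numbers pair the samples could not be settled. Same-numbered monolayer and bilayer arrays had deviations correlated at 0.053, 0.016 and 0.052 in adipocytes, all small. The value of -0.022 in macrophages cannot decide, because with 2 arrays in a group the deviations mirror each other. Each adipocyte bilayer array correlated best with its own number, a hint from the data only. With the replicate number as a block the counts were 1201 in adipocytes, 57 in macrophages, 238 in the difference and 16 higher in both, and 11, 8 and 11 lists. Of the alternatives written before the data were examined, those of no normexp correction, no between-array normalization, quantile normalization within a line, a detection p filter and the slide as a block were not run, since they need values that could not be tied to samples, and the authors' normalized values became the values tested. Signal over background limits dim genes, which have only bounds.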

Other observations

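The genes here were named after their values were seen and were tested as no group. The transferrin receptor gene Tfrc had a log2 difference of -0.62 in adipocytes and -0.61 in macrophages and passed the threshold in both, though in macrophages not without monolayer replicate 1 or either bilayer array (adjusted p = 0.0533 to 0.136). Hmox1, the haem oxygenase gene, rose by 1.79 in adipocytes and had a log2 difference of -0.33 in macrophages, which did not pass (adjusted p = 0.2). The metallothionein gene Mt2 rose by 1.60 and Mt1 by 0.40 in adipocytes. In macrophages the iron exporter gene Slc40a1 had a log2 difference of -0.74, and its call was lost without any 1 of the 4 macrophage arrays, at adjusted p = 0.0749 to 0.259.

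Mid1ip1 had a log2 difference of -0.25 in adipocytes and 0.41 in macrophages, and Lipa of 0.45 in adipocytes (0.29 without bilayer replicate 2) and -0.67 in macrophages. Hcar2, a receptor for hydroxybutyrate and nicotinic acid, rose by 0.51 in adipocytes and 0.51 in macrophages. Acss2 rose in both lines by 0.37 and 0.56. The Lipa, Acss2 and Mid1ip1 calls in macrophages were lost without any 1 of the 4 macrophage arrays, and that of Hcar2 without 3 of them (adjusted p = 0.073 to 0.184). In adipocytes the Mid1ip1 call was lost without 4 of the 6 arrays (adjusted p = 0.0592 to 0.0928) and that of Acss2 without 1 (adjusted p = 0.0633).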
